A study of Homo sapiens with 20 samples.

How the data were processed

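RNA of 10 human colorectal cancer cell lines (LoVo, COLO-201, LS1034, SNU-C1, HT-29, LS513, WiDr, HCT 116, LS123 and SW480) was sequenced from 2 compartments per line, as total RNA of the cells and as RNA of the extracellular vesicles that the cells released, giving 20 libraries. Extracellular vesicles are membrane-bound particles shed into the medium. Per the labels' protocols, the lines grew in RPMI-1640 or DMEM medium with fetal bovine serum. Cell libraries were made with a stranded kit that depletes ribosomal RNA, and vesicle RNA was isolated with an exosome RNA kit and amplified with a low-input SMART-Seq kit followed by Nextera tagmentation, per the labels' protocols. Compartment and library kit therefore coincide in every line, and no comparison of vesicles with cells can separate them.

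The deposited values are raw counts of reads per gene for 17113 protein-coding gene symbols, with no normalisation by the authors recorded in the sources used here. STAR, featureCounts and the hg19 build are named per the submitters' processing notes, with versions, annotation and strand setting not given in the sources used here. All 20 count columns carried a name that matched the title of 1 library, and 0 value columns were left unmapped. Reads of overlapping or antisense genes and of near-identical paralogs (histones, ribosomal proteins with processed pseudogenes, hemoglobin genes) cannot be told apart from the counts alone, and values of such genes are uncertain to that extent. Only protein-coding genes were listed, so other RNA classes were not analysed here. No hg19 annotation was used here, and no coordinates are given. Exonic length and GC content per gene came from GENCODE release 29, matched by symbol for 17104 of the 17113 genes (99.9%).

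Total counts ranged from 24.8 to 37.4 M in the cell libraries and from 1.75 to 24.4 M in the vesicle libraries. A gene with 0 counts could therefore still be present at up to 3 counts per library, which is 0.0802 to 0.121 CPM (counts scaled to library size) in cells and 0.123 to 1.72 CPM in vesicles. These limits cover counting error only, since reads without molecular identifiers are not independent molecules. The labels give 1 library per line and compartment, so the replicate is the cell line (n = 10), and spread between cultures of a line was not measured.

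Vesicles were compared with cells by the quasi-likelihood test of edgeR 4.0.16 (robust fit) in R 4.3.3, with TMM scaling, the filterByExpr filter and cell line as a block. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are vesicle over cell, and each SE is the absolute log2 fold change divided by the square root of the F statistic. The numbers pair the libraries because libraries of the same number come from the same cell line per the labels. The correlation of a line's deviations from the compartment means in cells and vesicles was 0.0846 to 0.546 over the 10 lines. The closest pairs of libraries within a compartment did not agree within sampling noise, which alone gives a chi-square per degree of freedom of about 1. It was 103 for HT-29 and WiDr cells, 249 for HCT 116 and LS123 cells and 259 for HT-29 and SW480 vesicles. Other pairs were not tested.

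The 26 gene lists, fixed before the data were examined together with the tests, the main settings and the rule for named genes, cover vesicle and endosome markers, cytosolic ribosomal proteins, translation factors, mitochondrially encoded mRNAs, the nuclear-encoded respiratory chain, replication-dependent histones, polyadenylated histone variants, intestinal epithelial identity, goblet and secretory genes, enterocyte genes, Wnt and stem cell genes, mesenchymal transition, interferon response, cell cycle, immediate early and stress genes, heat shock and chaperones, glycolysis, cholesterol synthesis, splicing factors, the proteasome, zinc finger genes, and markers of leukocytes, erythroid cells and platelets, hepatocytes and serum proteins, fibroblasts and endothelium, and keratinocytes. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count of 2) with a preset inter-gene correlation of 0.01, repeated with a correlation estimated per list. Camera compares the mean statistic of a list with that of all other genes, so its direction is relative to those genes and can differ in sign from the median of the list.

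The rule named the 12 largest rises and the 12 largest falls among genes past the threshold that had the same direction in all 10 lines and a mean of at least 10 CPM in the higher compartment, then CD9, CD63 and CD81, then the 2 members with the smallest adjusted p of each list. For agreement across lines it named the first 20 of the genes most variable in cells. A second set of 12 rises, limited to genes with a mean of at least 10 CPM in cells, was added after the data were seen, because the first set held genes with almost no reads in cells.

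Similarity of a vesicle library to its own line was measured as the Pearson correlation across genes of log2 CPM centred per gene within each compartment, minus the mean correlation with the 9 other lines. Agreement across lines was also measured gene by gene as the Pearson correlation over the 10 lines between cells and vesicles. Both were tested one-sided by permutations of the line labels of the vesicle libraries, 100000 for the values over all genes and 20000 for gene lists and alternatives. Paired values per line were tested two-sided by exact sign-flip permutation, for which 0.00195 is the smallest p that 10 pairs allow. Genes detected were those with at least 10 counts.

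After the data were seen, a background was estimated from 2077 genes with at most 10 counts in every cell library, called silent genes here. For each library the reads per exonic base over silent genes, in 10 bins of GC content, were multiplied by each gene's exonic length to give its expected background count. Alternatives chosen after the data were seen subtracted this expectation from every library or kept only the 5 lines with an estimated background under 10% of vesicle counts. Alternatives fixed earlier were no block for the cell line, DESeq2 1.42.0 size factors, library size only, upper-quartile scaling, no filter, a filter of at least 5 CPM in at least 10 libraries, the DESeq2 Wald test, limma-voom with quality weights, glmTreat, leaving out mitochondrial and ribosomal protein genes, leaving out each line, other prior counts and cutoffs, and thinning every library to the smallest total of 1748238 counts.

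The expression test was tested on simulated counts made from the real line means, library sizes and dispersions, with 200 genes changed. Of 50 genes raised 4-fold, 58.0% were called, and of 50 raised 2-fold, 10.0%. The corresponding shares for levels multiplied by 0.25 and 0.5 were 60.0% and 14.0%, and 2 of the unchanged genes were called among 14432 genes tested. Simulated levels were averaged over both compartments of a line, so they held no background particular to vesicles. The 2 false calls therefore do not cover rises from such background. Simulated vesicle libraries that carried a share of 0.5 or 1 of the line differences of the cells matched their own line in 10 of 10 lines over 15130 genes, and those that carried a share of 0 matched in 1.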

Results

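Transcript levels of 17113 protein-coding genes were measured in the cells and in the extracellular vesicles of 10 colorectal cancer cell lines, with 1 library per line and compartment. The series asks whether vesicle transcriptomes recapitulate those of their cells of origin. Each vesicle library was therefore set against the cells of its own line, and then against the cells of the other lines. Cell libraries held 31.1 ± 4.39 M counts (SD, n = 10) and vesicle libraries 9.11 ± 8.83 M, lower in 10 of 10 lines (exact sign-flip permutation p = 0.00195, two-sided). Vesicle depth differed between lines, from 1.75 M counts in SNU-C1 to 24.4 M in HT-29. The lines were not equally distant from one another. Among cell libraries, HT-29 and WiDr, lines known to come from the same donor, had a centred correlation of 0.805. HCT 116 and LS123 had one of 0.804, and the next pair 0.328. All tests and SDs treat the 10 lines as independent, which HT-29 with WiDr, and HCT 116 with LS123, may not be.

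Vesicle libraries covered nearly all genes detected in the cells of the same line, and many more besides. At least 10 counts were found for 12544 ± 387 genes in cells and 15443 ± 1079 genes in vesicles (SD, n = 10), higher in vesicles in 10 of 10 lines (exact permutation p = 0.00195, two-sided). Of the genes detected in a line's cells, 97.4% ± 2.86 (SD, n = 10) were detected in its vesicles, from 89.4% in HCT 116 to 99.0%. A further 3224 ± 859 genes per line were detected in vesicles and not in cells. Without HCT 116, whose vesicle library had the fewest genes detected, the share was 98.3%.

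Much of the excess consisted of a thin layer of reads over genes that the cells did not express. The 2077 silent genes, with at most 10 counts in every cell library, had a median of 16.4 ± 8.26 counts in vesicle libraries (SD, n = 10), against 0.2 ± 0.422 in cells. These counts rose with exonic length, from a mean of 9.10 in the shortest of 5 length classes of silent genes to 47.5 in the longest. Within each vesicle library, Spearman's rho of the counts with exonic length across silent genes was 0.289 to 0.645, where genes are not independent replicates. Scaled by length and GC content to all genes, these reads came to an estimated 18.1% ± 17.7 of vesicle counts (SD, n = 10) and 0.0971% ± 0.0433 of cell counts. The estimate was 50.3% in SNU-C1, 41.1% in LS123, 30.1% in WiDr, 23.4% in LoVo and 18.96% in LS1034. It was 7.11% in LS513, 3.40% in HCT 116, 2.52% in HT-29, 2.33% in COLO-201 and 2.05% in SW480. With this expected background subtracted, genes with at least 10 counts numbered 12395 ± 359 in cells and 11748 ± 959 in vesicles (SD, n = 10; exact permutation p = 0.0684, two-sided). The share of a line's cell-detected genes that were also detected in its vesicles was then 84.1% ± 8.45 (SD, n = 10).

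**Figure D1:**
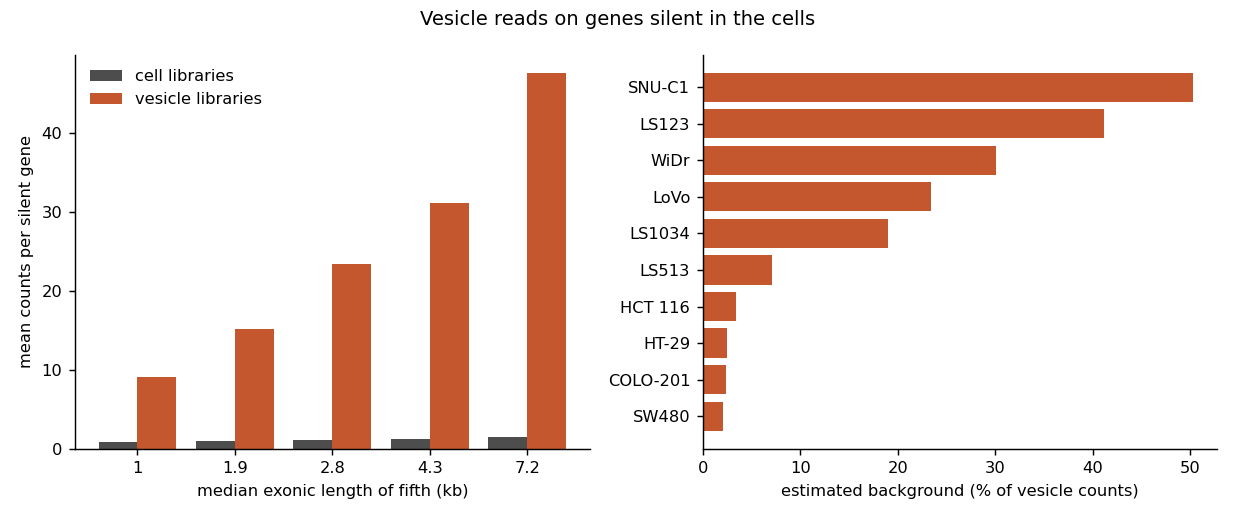
Left, mean counts per silent gene (y axis) in the 10 cell and the 10 vesicle libraries, for 5 classes of silent genes by exonic length (x axis, median in kb). Right, estimated background of each vesicle library in percent of its counts, from 2.05% in SW480 to 50.3% in SNU-C1.

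The 12 largest falls from cells to vesicles were led by SLC39A7, a zinc transporter of the endoplasmic reticulum, and TMEM30A, a subunit of membrane lipid flippases, at log2 fold changes of -4.78 (SE 0.63) and -4.49 (SE 0.31). TMEM30A stood at 277 ± 90.6 CPM in cells and 15.1 ± 12.4 CPM in vesicles (SD, n = 10, TMM-scaled). The amino acid transporters SLC7A5 (-4.20, SE 0.29) and SLC38A2 (-4.22, SE 0.39), the amyloid precursor protein gene APP (-4.24, SE 0.40) and the adherens junction cadherin CDH1 (-4.22, SE 0.41) fell to a similar degree. HSPA5, the main chaperone of the endoplasmic reticulum, went from 1641 ± 973 to 117 ± 93.2 CPM (SD, n = 10) at -3.99 (SE 0.40). SEL1L, PDIA3, SCD, ERMP1 and TGOLN2 made up the rest of the 12 largest falls, at log2 fold changes from -4.20 to -3.90. The 12 falls were seen in 10 of 10 lines each with TMM scaling, and by CPM of the library total in 11 of the 12, ERMP1 being higher in vesicles in 1 line. Their adjusted p ran from 6.27e-07 to 2.06e-05 in the quasi-likelihood test of edgeR. After background subtraction they stood at -7.70 for SLC39A7, whose vesicle level lay below the expected background, and at -4.21 to -3.23 for the others.

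The 12 largest rises were genes with almost no reads in cells. TMEM132E had 0 counts in all cell libraries together and 856 in the vesicle libraries, where the background model gave 749.8. AIRE, LILRB5 and ATP2B3 had 1, 2 and 2 counts in cells and 714, 805 and 977 in vesicles, against 574, 811 and 752 expected from background. CROCC2, AQP12B and COL20A1, with 4, 2 and 14 counts in cells, exceeded the expectation most, at 2.17, 2.29 and 2.48 times the expected counts. XIRP1, ADAM33, ITIH1, WDFY4 and ATP1A4 had 1 to 17 counts in cells. Over the 12 genes, chosen for their rise, the ratio of observed to expected counts had a median of 1.48 and ran from 0.992 to 2.48. After background subtraction XIRP1, CROCC2, ADAM33 and COL20A1 were still called higher (edgeR adjusted p from 0.000167 to 0.00275), and the others were not among the genes tested. Those still called passed the filter through their vesicle counts. No fold is given for these 12, whose cell levels lie at or near the counting limit.

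Among transcripts with a mean of at least 10 CPM in cells, a small set was far higher in vesicles. RAB13, a small GTPase of tight junction and vesicle traffic, went from 40.8 ± 14.4 CPM in cells to 3112 ± 2283 CPM in vesicles (SD, n = 10), a log2 fold change of 5.92 (SE 0.47, edgeR adjusted p = 9.38e-07). TRAK2, an adaptor for mitochondrial transport, rose by 4.22 (SE 0.55), the kinesin KIF1C by 3.88 (SE 0.42) and NET1, an exchange factor for RhoA, by 3.57 (SE 0.53). NET1 reached 5857 ± 5244 CPM in vesicles against 370 ± 252 CPM in cells (SD, n = 10). PITPNM3, a phosphatidylinositol transfer protein gene, rose by 4.20 (SE 0.47) and the kinase CDC42BPG by 3.28 (SE 0.33). The rises of these 6 genes were seen in 10 of 10 lines (9 of 10 for PITPNM3 after background subtraction), and with the background subtracted their log2 fold changes were 6.76 for RAB13, 5.02 for TRAK2, 4.71 for KIF1C, 4.38 for NET1, 4.50 for PITPNM3 and 3.96 for CDC42BPG. TH, COL4A1, ACSL6, PARVB, IGFL2 and GMFG, the remaining 6 of the 12, rose by 3.26 to 4.84 on the log2 scale from means carried by few lines. After background subtraction COL4A1 was not among the genes tested, PARVB was not called (2.30, adjusted p = 0.176) and the 4 others were. These 6 did not pass the threshold without the cell line block (adjusted p from 0.298 to 0.775, edgeR), and PARVB also not without LS1034, SNU-C1, HT-29 or LS513 (0.0505 to 0.0651).

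**Figure D2:**
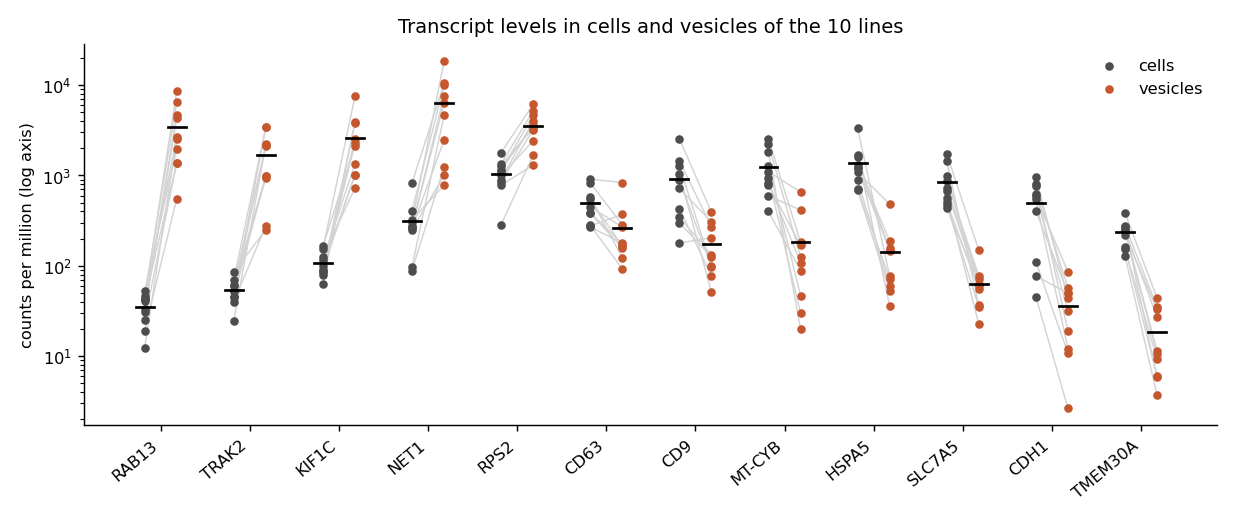
CPM of the library total (log axis) in cells and vesicles of the 10 lines for 12 transcripts (x axis). Points are libraries, grey lines join the libraries of a line and black bars are means over 10 lines. RAB13, TRAK2, KIF1C and NET1 lie higher in vesicles in 10 of 10 lines, and HSPA5, SLC7A5, CDH1 and TMEM30A lower in 10 of 10.

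In all, 4322 genes were higher and 4254 lower in vesicles among 15130 tested (edgeR, adjusted p under 0.05), and 4078 and 2934 of these differed by at least 2-fold. Of 2401 tested genes with a mean under 1 CPM in cells, 2308 were higher and 0 lower. This direction was set largely by the expression filter and is no result: 3 of the 2401 (FAM229A, STAG3 and MTRNR2L10) reached its limit of 0.407 CPM in every cell library, and the others needed their vesicle counts to pass. They include 614 of the 2077 silent genes, all higher. Of 10024 genes with at least 10 CPM in cells, 530 were higher and 4235 lower. With the background subtracted, 1842 genes were higher and 2543 lower, sharing 1029 and 2214 genes with the first fit. Within the 5 lines of lower background, 2881 were higher and 2816 lower, sharing 2242 and 2554. The balance also depended on scaling: the median log2 fold change of all genes was 0.01 with TMM, 0.38 with DESeq2 size factors, 0.48 with library size only and 0.76 with upper-quartile scaling. Of all calls, 50.4% were higher with TMM, 65.5% with DESeq2 size factors (5325 higher and 2802 lower), 69.2% with library size only (5532 and 2465) and 79.8% with upper-quartile scaling (6957 and 1759). Leaving out LoVo alone moved the median to 0.35 and the counts to 4749 higher and 2383 lower. The changes of gene lists below are relative to all genes, as camera tests them, and no call of a list held with an estimated correlation (adjusted p from 0.442 to 0.968 over the 26 lists).

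Vesicle and endosome markers were not enriched in the vesicle RNA. Of 24 members 0 rose and 19 fell (20 adjusted over the list alone), with a median log2 fold change of -1.33 (camera adjusted p = 2.36e-05). The tetraspanins CD9, CD63 and CD81, whose proteins mark vesicle membranes, changed by -2.68 (SE 0.44), -1.51 (SE 0.28) and -1.86 (SE 0.21) on the log2 scale, with a fall in 10 of 10 lines each under TMM scaling. By CPM of the library total CD9 and CD63 were each higher in vesicles in 1 line, and after background subtraction in 1 and 2 lines. The lysosomal membrane genes LAMP1 (-3.03, SE 0.24) and LAMP2 (-3.74, SE 0.34) had the smallest adjusted p of the list. Background subtraction left 1 member that rose and 9 that fell (median -0.66, camera adjusted p = 0.0318).

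Mitochondrially encoded mRNAs fell together. All 13 were lower in vesicles (13 adjusted over the list alone), with a median of -3.22 (camera adjusted p = 2.43e-05), and MT-CO2 and MT-CYB fell by 3.78 each (SE 0.60). They made up 0.865% ± 0.364 of counts in cells and 0.196% ± 0.196 in vesicles (SD, n = 10), lower in 10 of 10 lines (exact permutation p = 0.00195, two-sided). Background subtraction left 12 of 13 that fell (median -2.39). Transcripts of the nuclear-encoded respiratory chain did not follow: 3 of 61 rose and 7 fell (0 and 2 adjusted over the list alone), with a median of 0.06 and a mean of 0.01, while the direction of the camera test was lower (adjusted p = 0.646). With the background subtracted 39 of 61 rose and 2 fell (median 0.81, camera adjusted p = 2.69e-08), and in the 5 lines of lower background also 39 and 2.

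Ribosomal protein mRNAs were higher in vesicles. Of 79 members 14 rose and 0 fell (0 and 0 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.00782). RPS2 went from 1233 ± 463 to 3141 ± 1390 CPM (SD, n = 10; log2 fold change 1.30, SE 0.31) and RPSA from 342 ± 145 to 808 ± 461 CPM (1.13, SE 0.29), each higher in 9 of 10 lines. Together they took 3.92% ± 1.14 of counts in cells and 8.71% ± 3.48 in vesicles (SD, n = 10), higher in 9 of 10 lines (exact permutation p = 0.00586, two-sided). After background subtraction 76 of 78 rose (median 1.38), and in the 5 lines of lower background 77 of 79 rose (median 1.34). For the cytosolic ribosomal proteins the camera adjusted p was 0.0601 without SW480, at a median of 0.48, and ran from 9.90e-28 to 0.0749 over the alternatives. Of 21 translation factors 1 rose and 3 fell (0 and 2 adjusted over the list alone; median -0.19, camera adjusted p = 0.447), and with the background subtracted 8 rose and 3 fell, EIF4G1 among them at -1.31.

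Sterol synthesis genes fell: 16 of 23 were lower and 1 higher (16 and 1 adjusted over the list alone; median -1.29, camera adjusted p = 2.6e-05), with the master regulator SREBF2 at -2.64 (SE 0.24). Background subtraction left 11 that fell and 0 that rose at the same median. Cell cycle genes fell in 24 of 36 cases with 0 rises (25 adjusted over the list alone; median -1.09, camera adjusted p = 2.36e-05), including the proliferation marker MKI67 (-2.27, SE 0.29) and the spindle motor KIF11 (-2.21, SE 0.25). Of 36 splicing factor genes 24 fell and 1 rose (24 and 1 adjusted over the list alone; median -0.88, camera adjusted p = 2.36e-05), with PRPF8 at -2.87 (SE 0.22) and SNRNP200 at -2.48 (SE 0.24). After subtraction the camera adjusted p was 0.0880 for cell cycle (14 fell, 1 rose) and 0.269 for splicing (11 fell, 4 rose), with means that went from -1.06 (SD 0.67 over members) to -0.41 (SD 0.70) and from -0.97 (SD 0.81) to -0.43 (SD 0.97). Both remained called lower in the 5 lines of lower background, cell cycle at 0.00148 (median -0.67) and splicing at 0.00876 (median -0.40).

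The remaining lists that fell lost their call once the background was subtracted, in part because the genes they are compared with moved: the mean camera statistic of all other genes went from 0.69 to between -0.467 and -0.465. Of 27 intestinal epithelial identity genes 8 fell (7 adjusted over the list alone), CLDN7 by 2.68 (SE 0.28), with a median of -0.71 (camera adjusted p = 0.0226). After subtraction 6 fell and 1 rose (median -0.49, camera adjusted p = 0.489), and the mean went from -0.92 (SD 1.24 over members) to -0.63 (SD 1.16). Without SNU-C1 the camera adjusted p of intestinal epithelial identity was 0.0695, and over the alternatives it ran from 0.00055 to 0.489. Glycolysis fell in 12 of 23 (12 adjusted over the list alone; SLC2A1 -3.00, HK2 -1.92; median -0.80, then -0.36; mean -0.70, SD 0.79, then -0.39, SD 0.92; camera adjusted p = 0.0106, then 0.678). Heat shock and chaperone genes fell in 9 of 20 (7 adjusted over the list alone; HSPA4 -1.54, BAG3 -1.25; median -0.78, then 0.02; mean -0.77, SD 0.43, then 0.005, SD 0.47; camera adjusted p = 0.00460, then 0.528). Immediate early and stress genes fell in 11 of 28 and rose in 2 (11 and 2 adjusted over the list alone; HSPA5 and XBP1, at -2.46, first; median -0.71, then -0.50; mean -0.54, SD 1.53, then -0.51, SD 1.27; camera adjusted p = 0.0232, then 0.382). The lost calls of intestinal identity and of immediate early genes therefore do not show that their fall was background. With upper-quartile scaling the medians of intestinal identity and of immediate early genes were 0.04 each, so that their direction holds only relative to all genes. All genes include those that needed their vesicle counts to pass the expression filter. Of 10064 genes that reached its limit of 0.407 CPM in every cell library, 4234 fell (median -0.51). Such members fell in 9 of 20 cases for heat shock and chaperones (median -0.78) and 11 of 24 for immediate early genes (-0.78), near that share. Glycolysis had 12 falls in 20 (-0.83) and intestinal identity 8 in 12 (-1.22).

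Lists of markers of other cell types, called foreign here, had reads in vesicles, as the silent genes did. Not every member was absent from the cells: LYZ stood at 2728 CPM in HT-29 cells and KRT5 at 1645 CPM in SW480 cells. Of 15 fibroblast and endothelial markers 12 rose (12 adjusted over the list alone; median 6.21), of 12 hepatocyte and serum protein genes 10 (10; median 5.03), of 9 erythroid and platelet markers 8 (8; median 4.72), of 11 keratinocyte markers 8 (9; median 4.67) and of 14 leukocyte markers 12 (12; median 4.37), with 0 falls. This direction was largely set by the expression filter, and the camera test of these 5 lists (adjusted p from 2.36e-05 to 0.00105) is no evidence of a rise: their median members had 0.349 to 0.909 CPM in cells, and 1 member, KRT10, which was not called (0.12), reached the limit of the filter in every cell library. COL6A3 had 2392 counts in the vesicle libraries together where the background model gave 1679, APOB 819 where it gave 683, and THY1 637 where it gave 592. KRT2, ITGA2B, CSF1R, APOC3 and KRT16 had 1.27, 1.36, 1.77, 1.85 and 2.62 times the expected counts. GNG11 had 27.5 times, but 3532 of its 3864 counts came from SW480, whose cells express it at 84.6 CPM, and without SW480 the ratio was 2.46. Enterocyte genes (8 of 19 rose, 1 fell; AQP8 and CA4 first; 8 and 1 adjusted over the list alone; median 1.72, camera adjusted p = 0.0180) and mesenchymal transition genes (8 of 19 rose, 0 fell; TAGLN and ZEB2 first; 8 adjusted over the list alone; median 2.33, camera adjusted p = 0.0129) had the same direction, but 3 and 5 of their members reached that limit in every cell library, with medians of -1.11 and 0.67 and 0 rises. After subtraction the medians of the 2 lists were 0.47 and 0.77 and their adjusted p 0.174 and 0.0835. Of the 5 foreign lists, 5 to 8 members then passed the filter, too few and too near the counting limit to settle whether a rise was left (medians from 2.43 to 5.70, adjusted p from 0.00187 to 0.0576).

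None of the other lists passed the camera test with counts as deposited. Replication-dependent histones, which lack a poly(A) tail, had 3 rises and 0 falls in 20 (2 adjusted over the list alone; H2BC18 and H2AC21 first; median 0.62, adjusted p = 0.160), and polyadenylated histone variants 3 falls in 10 (1; H1-10 -0.87; median -0.27, adjusted p = 0.179). Goblet and secretory genes had 7 rises in 15 (5; MUC5B and MUC5AC first; median 1.68, adjusted p = 0.170), and the proteasome 4 falls in 30 (4; PSMD1 -1.49, PSMD2 -1.16; median -0.34, adjusted p = 0.0578). Background subtraction made both called higher by camera, goblet and secretory genes at an adjusted p of 0.0465 (median 1.32) and the proteasome at 0.00252 (median 0.45). With an estimated correlation neither call held (camera adjusted p = 0.515 and 0.566). MUC5AC was not called after subtraction (edgeR adjusted p = 0.255), while MUC5B was (6.94). Wnt and stem cell genes had 9 falls and 1 rise in 23 (9 and 1; SOX9 -2.64, BMP4 -1.72; median -0.38, adjusted p = 0.0948, and 0.0101 with the background subtracted). Interferon response genes had 5 falls and 2 rises in 27 (5 and 1; TAP1 -3.67, OAS3 -1.48; median -0.11, adjusted p = 0.262). Zinc finger genes had 88 rises and 76 falls in 430 (79 and 68; ZNF536 and ZNF835 first; median 0.08, mean 0.76, adjusted p = 0.880), and were called lower with the background subtracted (median -0.63, adjusted p = 0.0465) and in the 5 lines of lower background (-0.34, 0.0332). The expression filter bears on the rises and on the medians of these lists. Members below its limit of 0.407 CPM in any cell library needed their vesicle counts to pass. Of 15 goblet and secretory genes 1 reached the limit in every cell library and was not called (-0.74). The 12 replication-dependent histones that reached it had 0 rises. The 279 zinc finger genes that did had 19 rises and 74 falls. The 11 Wnt and stem cell genes that did had 0 rises and 8 falls, with a median of -1.72. The call of H1-10 was lost without LoVo, LS1034, WiDr or LS123 (adjusted p from 0.0551 to 0.256). Single lines also decided 3 of the lists: replication-dependent histones were called higher without SNU-C1 (adjusted p = 0.0199), as they were with limma-voom (0.0263) and in the 5 lines of lower background (5 rises, median 0.95, 0.00232), Wnt and stem cell genes lower without LoVo (0.0252) or LS123 (0.0372), and the proteasome lower without COLO-201, HT-29, LS513, HCT 116 or SW480 (0.0177 to 0.0425). With upper-quartile scaling the medians of polyadenylated histone variants (0.47), the proteasome (0.40), Wnt and stem cell genes (0.35), interferon response genes (0.64) and translation factors (0.54) lay above 0, with the median of all genes at 0.76 there. Relative to that median they stayed below 0, at -0.28, -0.35, -0.40, -0.12 and -0.21. This sign depends on the filter. With TMM, genes that reached its limit in every cell library had a median of -0.51. Such members lay above it for polyadenylated histone variants (-0.27), the proteasome (-0.34), interferon response genes (-0.17) and translation factors (-0.19). Those of Wnt and stem cell genes lay below it.

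**Figure D3:**
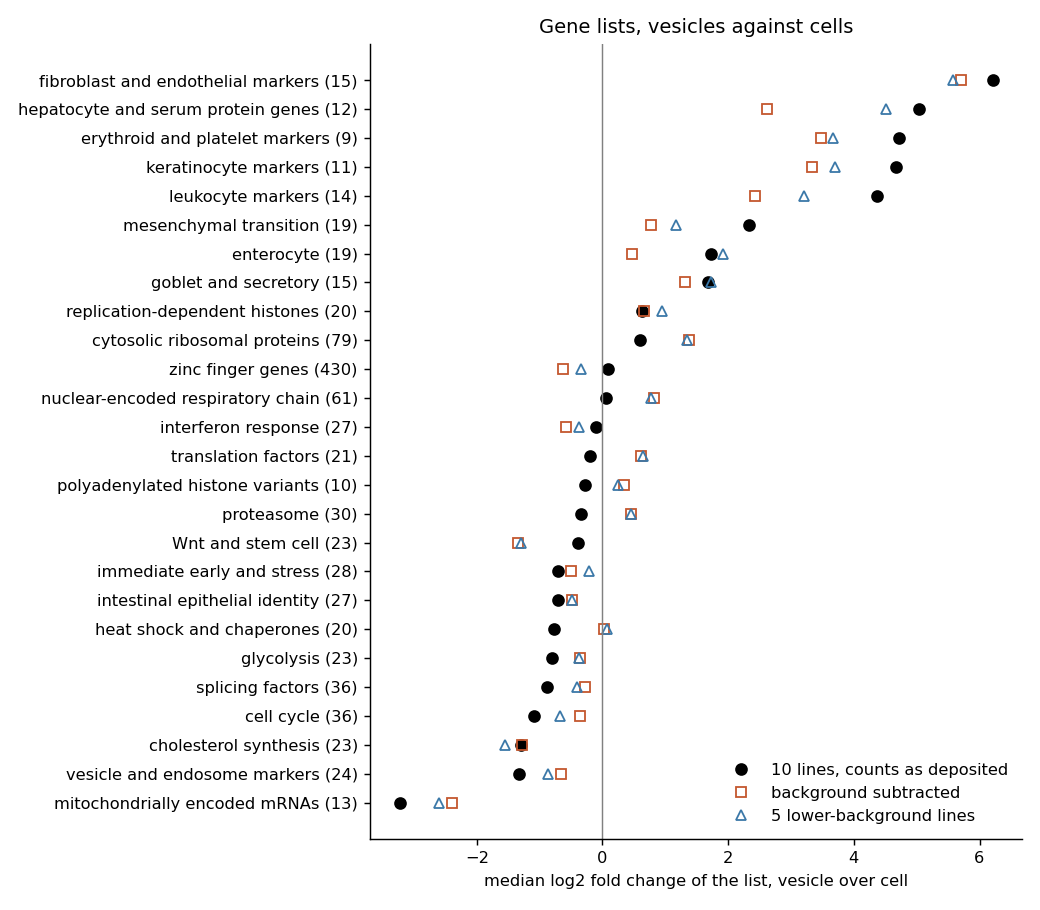
Median log2 fold change, vesicle over cell (x axis), of the 26 gene lists (y axis, number of tested members in brackets). Filled circles are the 10 lines with counts as deposited, squares the background-subtracted counts and triangles the 5 lines of lower background. Ribosomal proteins move from 0.59 to 1.38 and 1.34, and mitochondrially encoded mRNAs stay lowest in each.

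The next question was whether a vesicle library resembles the cells it came from more than the cells of other lines. After centring each gene within its compartment, 9 of 10 vesicle libraries had their highest correlation across genes with the cells of their own line. The correlation with the own line exceeded the mean over other lines by 0.420 ± 0.159 (SD, n = 10; permutation p = 1e-05, one-sided, the smallest that 100000 permutations can give). Own-line values ran from 0.546 in LS513 and 0.514 in HT-29 to 0.0846 in SNU-C1, the library with the highest background estimate (50.3%). SNU-C1 vesicles were closest to LS123 cells at 0.0885 and next to their own. HT-29 and WiDr, lines of the same donor, were still told apart as single cultures. HT-29 vesicles correlated at 0.514 with HT-29 cells and at 0.397 with WiDr cells. WiDr vesicles correlated at 0.238 with WiDr cells and at 0.114 with HT-29 cells. The own-line value was the highest in either case. With 1 library per line and compartment, a difference between lines cannot be told from one between cultures.

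**Figure D4:**
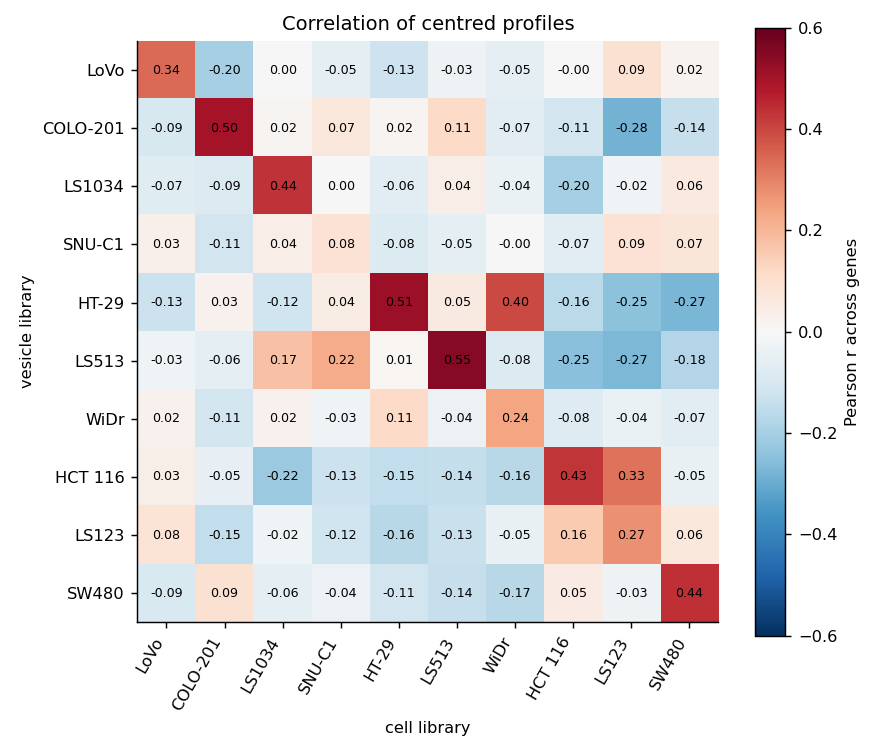
Pearson correlation across genes between centred profiles of the vesicle library (y axis) and the cell library (x axis) of each of the 10 lines. The diagonal holds the highest value for 9 of 10 vesicle libraries, the exception being SNU-C1.

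By absolute levels, 9 of 10 vesicle libraries were closest to their own cells. The exception was HCT 116, whose vesicles had a rho of 0.853 with LS123 cells and 0.849 with their own. Spearman's rho across genes between vesicles and own cells was 0.776 ± 0.128 and with the cells of other lines 0.697 ± 0.112 (SD, n = 10; exact permutation p = 0.00195, two-sided). Own-line rho was 0.904 in HT-29 and SW480, 0.876 in COLO-201, 0.849 in HCT 116 and 0.831 in LS513, and it was 0.746 in LS1034, 0.739 in LoVo, 0.728 in WiDr, 0.700 in LS123 and 0.482 in SNU-C1. Across lines it fell with the background estimate, at Pearson r = -0.945 (permutation p = 1e-05, adjusted 3e-05 over 3 relations) and Spearman rho = -0.988 (p = 2e-05, adjusted 4.5e-05), with r = -0.953 without SNU-C1 and LS123. Own-line rho rose with log2 vesicle depth (Pearson r = 0.851, permutation p = 0.00014, adjusted 0.00021). The background estimate itself fell with log2 vesicle depth (Pearson r = -0.868, permutation p = 0.00162, adjusted 0.00162). Its Spearman rho with depth was -0.952 (permutation p = 1e-04, adjusted 1e-04), and r was -0.878 without HT-29 and SW480. These correlations therefore cannot separate depth from background over the 10 libraries. With every library thinned to 1748238 counts, own-line rho still ran from 0.425 in SNU-C1 to 0.835 in SW480. Its SD was then 0.117, against 0.128 as deposited, so the number of reads alone is argued against as the source of the spread.

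Genes that set the lines apart in cells tended to do so in vesicles. The Pearson correlation over the 10 lines between cells and vesicles averaged 0.345 over 15130 genes (permutation p = 1e-05, one-sided), and 84.5% of genes were above 0. For the 1000 genes most variable in cells it averaged 0.569 (permutation p = 1e-05), with 96.0% above 0. Mean Spearman rho was 0.321 and 0.528 (permutation p = 1e-05 each), and without the 2 lines farthest from each gene's median the mean Pearson r was 0.256 and 0.434. Intestinal epithelial identity genes averaged 0.737, with 27 of 27 above 0 (mean rho 0.711; 0.632 without the 2 lines per gene), and goblet and secretory genes 0.690, with 14 of 15 above 0 (mean rho 0.697; 0.630). Wnt and stem cell genes averaged 0.615 with 23 of 23 above 0 and interferon response genes 0.605 with 27 of 27 above 0. The permutation p of these 4 lists was 5e-05, the smallest that the 20000 permutations used for lists can give, and 0.000144 after adjustment over 26 lists. Mitochondrially encoded mRNAs did not follow the cells at all: they averaged -0.311 with 0 of 13 above 0 (p = 0.842, adjusted 0.842, one-sided; mean rho -0.319). Cytosolic ribosomal proteins (mean 0.269, 69 of 79 above 0, p = 0.130, adjusted 0.136; mean rho 0.386, p = 0.0159) and replication-dependent histones (mean 0.185, p = 0.0792, adjusted 0.0858) did not pass either. For the other lists adjusted p was at most 0.0262. In the 5 lower-background lines, where lists were not called, ribosomal proteins averaged 0.644 and replication-dependent histones 0.517. Mitochondrially encoded mRNAs averaged -0.639 there, and all genes 0.449.

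Single genes carried the mark of their line. Of the 50 genes most variable in cells, 20 peaked in the same line in cells and vesicles, against 5.01 under permutation of the lines (permutation p = 0.00028, one-sided). Among the first 20 of them these were CCND2 and SPINK1 in LS1034, LYZ in HT-29, IL33 and TFF3 in LS513, REG4 in LoVo and SLC2A3 in SW480. REG4, a secreted lectin of goblet and endocrine cells, stood at 1292 CPM in LoVo cells and a median of 0.242 CPM in the other cells, and at 499 CPM in LoVo vesicles and a median of 14.2 CPM in the others. IL33, an alarmin cytokine, stood at 1459 CPM in LS513 cells and 1024 CPM in LS513 vesicles, against medians of 0.930 and 13.3 CPM elsewhere. SPINK1 was at 425 CPM in LS1034 cells and 779 CPM in LS1034 vesicles, against medians of 20.2 and 11.4 CPM. TM4SF4 and LGALS4, highest in WiDr cells, were highest in HT-29 vesicles, the line of the same donor. AGR2, CDH17, CEACAM5, CEACAM6, GPX2, STYXL2, ATP10B, CFTR, LRATD1, TSPAN8 and STC2 also peaked in another line in vesicles. In 32 of the 50 genes the top line of the cells ranked first or second in vesicles.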

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

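The length test of the silent genes and both tests of the RAB13 group were chosen after the results were seen, as were the limit of 10 CPM in the test of solute carriers, the background subtraction and the use of 5 lower-background lines.

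Genes that were silent in the cells had reads in the vesicle libraries, and these reads are in line with a background spread over exons. Their counts rose with exonic length in each of the 10 vesicle libraries, with the lowest Spearman's rho across genes at 0.289. The 23 silent markers of other cell types had a median of 1.10 times the reads expected from length and GC content. Of them 1, AHSP, exceeded a ratio of 2. Human RNA shared among these cell types is thereby argued against as the whole source, but a median over several cell types could miss a single one. The markers are human genes, so RNA of the bovine serum in the medium was not tested. Abundant transcripts of such cells that were not silent went higher in 5 of 6 cases: HBB had 1294 reads against 112 expected (721 against 97.6 without LS123), ALB 344 against 146, HBA1 236 against 102, HBA2 256 against 101 and COL1A1 2241 against 1135, while PTPRC had 316 against 325, so a share of RNA from blood, liver or stroma stays open. Whether the background came from DNA, from the amplification or from the vesicles themselves was not tested, and no biological explanation was tested.

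HSPA5, PDIA3, SEL1L and SLC7A5, among the 12 largest falls, encode proteins of the secretory pathway, a theme read from these genes and not tested on a fixed list, and a candidate explanation is that mRNAs translated at the endoplasmic reticulum enter vesicles less often. The test set solute carriers, whose mRNAs are mostly translated there, against SLC25 carriers, which are made in the cytosol, and the difference of their median log2 fold changes was 0.14 (274 and 44 genes, permutation p = 0.765, two-sided), which by itself argues against it. That bound did not allow for the background, which raises the 115 solute carriers under 10 CPM in cells: at 10 CPM or more the difference was -0.80 (permutation p = 0.00425), and with the background subtracted -1.08 (p = 0.0120). The subtraction met the bound set against background as the cause, but it cannot decide: no deficit was there before it, background adds reads to vesicle libraries, and its removal takes proportionally more from weakly expressed genes. Removing the trend with exonic length and GC content left -0.99 (permutation p = 0.0120), so such a trend is argued against as the whole cause of the difference after subtraction, while the 5 lower-background lines gave -0.67 (p = 0.164). All permutations of the solute carriers shuffled the family labels among genes, which are not independent replicates, and spread over the lines does not enter p. The explanation stays open, since the tests disagree and the library kits differ between the compartments in every line.

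RAB13, NET1, KIF1C and TRAK2, whose mRNAs belong to a class localised to cell protrusions, were far higher in vesicles. Background reads are argued against, since with them subtracted the smallest of the 4 log2 fold changes was 4.38. An enrichment of the class as a whole stays open. PKP4, KANK2, DDR2, CYB5R3, INPP1 and PALLD had a median of 0.16 with the background subtracted. Of these 6, 1 (PALLD, 1.30) was called higher. These values met the bound set against an enrichment of the class, but the 6 leave out the 4 called members. Over all 10 the median was 1.89, with 5 called higher, which cannot count for the class, since the 4 were picked for their rise in these data. Neither value can therefore decide. DDR2, at 0.705 CPM in cells, was called as deposited (3.51, adjusted p = 0.00105, higher in 10 of 10 lines) and not after subtraction (2.47, adjusted p = 0.134). A selection of these 4 transcripts and an effect of the library kits remain open as well.

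The real pairing of compartments gave 8576 genes past the threshold, and 1 of 25 splits that swap the compartments within lines, the real one, gave as many. The highest of the others gave 4830 genes and differed from the real split by 1 line, and 22 of the other 24 gave 0. Chance is argued against, but 25 splits are too few to exclude it. The splits also cannot separate compartment from library kit.

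Among 104 groups of 10 libraries or lines, 7 held a value far from the others, where chance gives about 1 in 20, or 5.2. HCT 116 vesicles had 12622 genes with at least 10 counts, against 15002 in the next library. They also covered 89.4% of the genes detected in their cells, against 97.1% in the next line. LoVo cells had 6.59% of counts in ribosomal protein genes, against 4.40% in the next library. SNU-C1 had an own-line rho of 0.482, against 0.700 in the next line. The log2 difference of CDH1 was -1.48 in LS123 and from -5.72 to -3.56 in the other lines. That of BAG3 was 0.38 in SW480 and from -1.84 to -0.66 in the others, and that of GNG11 0.96 in SW480 and from 3.30 to 5.78 in the others.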

How the results depend on the processing

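The background subtraction and the use of only the 5 lower-background lines, samples selected by a technical measure, were alternatives chosen after the data were seen.

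Named genes held their direction under the alternatives wherever they were tested. Of 1815 values of 89 genes, 1776 stayed on the same side of the threshold, 39 lost the call and 0 changed sign. The naming rule largely set this, since most were picked for the same direction in all lines or the smallest adjusted p. A gene that failed the filter under an alternative gives no value there. With the background subtracted, TMEM132E, AIRE, LILRB5, APOB and THY1 were among those not tested. Of 539 values of gene lists, 483 stayed on the same side, 27 lost the call, 20 gained one and 9, called before or after, reversed the direction of the camera test. Counting also values not called on either side, 31 values of 7 lists had the other direction. Without the cell line block 3470 genes were higher and 3438 lower, against 4322 and 4254 with it.

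The number of genes higher in vesicles moved to 6957 with upper-quartile scaling, 2411 with the stricter filter (10991 genes tested), 1842 with the background subtracted (12736 tested) and 2881 in the 5 lower-background lines. The number lower moved to 2802 with DESeq2 size factors, 2465 with library size only and 1759 with upper-quartile scaling, where the median of all genes shifts upward. It was 2060 with the stricter filter, 1535 with glmTreat, which tests against a minimum fold, 2543 with the background subtracted and 2816 in the 5 lines. Genes higher by at least 2-fold numbered 1703 with the stricter filter, 1352 with the background subtracted and 2487 in the 5 lines, against 4078. Genes lower by at least 2-fold, 2934 as reported, numbered 1745 with DESeq2 size factors, 1494 with library size only, 971 with upper-quartile scaling, 1268 with the stricter filter, 1800 with the DESeq2 Wald test and 1535 with glmTreat. Leaving out each line gave 3895 to 4749 genes higher, 2383 to 4277 lower, 3734 to 4454 higher by at least 2-fold and 1722 to 3159 lower by at least 2-fold. Both low values, 2383 and 1722, came without LoVo. Beyond the number of genes or lines tested, the cause of these moves was not tested.

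Lists higher in vesicles numbered 8, 5 of them marker lists whose direction the filter largely set, and 3 with the stricter filter and 7 to 9 without each line, and lists lower numbered 9, 5 with the stricter filter, 5 with the background subtracted and 8 to 10 without each line. The stricter filter removes the genes near the counting limit. The camera direction of 5 lists reversed with a call before or after, of which heat shock and chaperones was the one called with counts as deposited. Translation factors had a median of 0.61 with the background subtracted and 0.64 in the 5 lines, and the nuclear-encoded respiratory chain 0.59 with the stricter filter, 0.81 with the background subtracted and 0.78 in the 5 lines. Heat shock and chaperones stood at 0.0197 and the proteasome at 0.45 with the background subtracted, and zinc finger genes at -0.63 with it and -0.34 in the 5 lines.

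Own-line similarity was 0.405 to 0.470 without each line, with 8 to 9 of 9 libraries closest to their own cells. In the 5 lower-background lines own-line similarity was 0.698 and 5 of 5 were closest, and with thinning or the background subtracted 10 of 10. It was 0.711 over the 1000 most variable genes and 0.378 with Spearman correlation. Own-line rho was 0.764 to 0.808 without each line, with 0.686 to 0.725 for other lines. In the 5 lines it was 0.870 at an exact permutation p of 0.0625, the smallest that 5 pairs allow. Gene-wise agreement without each line was 0.330 to 0.387 over all genes and 0.538 to 0.605 over the 1000 most variable, and 19 to 27 top lines matched. The excess of detected genes in vesicles, 2899, was 2786 to 3211 without each line and reversed to -646.7 with the background subtracted (exact permutation p = 0.0684). The share of cell-detected genes seen in vesicles was 97.2% to 98.3% without each line and 84.1% with the background subtracted. Depth sets a lower limit: a count of 0 still allows up to 1.72 CPM in the smallest vesicle library and up to 0.121 CPM in the smallest cell library.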

Other observations

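The comparisons of cell libraries here were chosen after the data were seen. The cells of HCT 116 and LS123, which the labels give as separate lines, were about as close to each other as those of HT-29 and WiDr, which share a donor. Of 10024 genes with at least 10 CPM in cells, 77 differed at least 4-fold between HCT 116 and LS123 and 124 between HT-29 and WiDr. The third lowest of the 45 pairs had 724 such genes, and the median pair 1201. The chi-square per degree of freedom between the cell libraries was 249 for HCT 116 and LS123 and 103 for HT-29 and WiDr, so neither pair agreed within sampling noise. HCT 116 vesicles had a centred correlation of 0.427 with their own cells and 0.326 with LS123 cells, and LS123 vesicles 0.273 with their own and 0.159 with HCT 116 cells. By Spearman's rho of levels across genes, HCT 116 vesicles stood at 0.849 with their own cells and 0.853 with LS123 cells. Whether each library comes from the line that its label names was not tested.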
